A study of Mus musculus with 49 samples.

How the data were processed

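Frontal cortex of mice on a high fat diet was profiled by RNA sequencing. Per the labels' protocols, total RNA was isolated from the frontal cortex and libraries were made with the Illumina TruSeq Stranded mRNA kit. Each of the 49 libraries was placed in 1 of 5 groups by its title, and the group titles are spelled out in the series' design text. The labels give no sex, strain, litter, collection time or sequencing batch. The titles carry numbers but do not say what a number stands for, so p-values measure the spread between these libraries.

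The authors deposited 1 table of log2 values for the whole series, with 24495 genes and 50 value columns. The steps behind it are not given in the sources used here, which name no aligner, counter, genome build or normalization tool. The values themselves were tested for their unit. After 2 was raised to the deposited log2 value and 1 was subtracted, the low values of each column, up to 200 reads, fell on whole multiples of a single step. The share within 0.1 of a whole number of reads was 99.92% to 100.00% per library. The steps differed from median-of-ratios size factors computed on the recovered reads by at most 0.041%. The deposited value is therefore log2 of a read count divided by a size factor, plus 1, and the reads behind each value could be recovered. A fold change on this log2(value + 1) scale understates the change of genes with few reads.

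A single value column matched no sample in the labels and was not used in any step (1 unused column). Values of 7 genes were not whole reads in at least 1 column and were left out. Gene symbols that a spreadsheet had turned into dates (27) were restored from their gene IDs. Positions were taken by symbol from GENCODE M21 (GRCm38), in which 23464 genes of the table had a single position; the build behind the deposited values is not given in the sources used here.

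Recovered reads per library ranged from 29.2 to 75.6 M (M for 1e+06), with a median of 42.0 M, and 17089 to 18787 genes had a read. Limits from counts of 0 use 3 reads over a group and cover counting error only. Replicates were compared before averaging with a chi-square test of recovered reads, and the closest pair in any group still differed by 7.05 per gene, where sampling noise alone gives about 1, so no library was treated as a duplicate.

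The tests planned before the data were examined assumed counts. Because the deposited unit was log2, the planned fallback was used as the main test: limma 3.58.1 in R 4.3.3 with an intensity trend and robust variance shrinkage, on the deposited values, fitted to the groups compared alone, with Benjamini-Hochberg adjustment, two-sided, at adjusted p 0.05. No covariate or block was used. Genes were tested if they reached the equivalent of 10 reads at the median library in as many libraries as the smaller group and 15 reads in total. The 4 comparisons were tamoxifen against vehicle in the conditional human amylin mice, libraries labelled AKO against WT at 4 months, WT at 4 against 2 months, and vehicle-treated transgenic mice against WT at 4 months. All of these but tamoxifen against vehicle use the same WT libraries at 4 months, so their results are not independent. The difference between the effect in the libraries labelled AKO and that of tamoxifen was tested in 1 model of 4 groups.

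Gene groups were 35 lists of cell type markers, brain region markers and pathways fixed before the data were examined. A list was tested with limma camera at a preset inter-gene correlation of 0.01 if at least 5 members were tested, and again with the correlation estimated from the residuals. Members past the gene test were counted over all genes tested and adjusted over the list alone. Genes were named by a rule fixed beforehand: Iapp first, then the 8 largest rises and 8 largest falls past the threshold with a mean of at least 1 CPM of recovered reads and a symbol that is not a predicted model, and up to 3 members of each list past the threshold with the smallest p. Where fewer than 5 genes passed, the 5 with the smallest p in each direction were named as not passing. A gene named outside this rule is said to be chosen after its values were seen. List levels used as covariates or plotted are means of z-scores of the deposited values.

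The gene test was run on simulated reads drawn from the real means and depths, with known changes in about 200 genes. For libraries labelled AKO against WT, on 15067 simulated genes, 80.0% of genes changed 1.5-fold and 94.0% of those changed 2-fold were recovered, and 5.1% of the 176 calls were wrong. For WT at 4 against 2 months, 77.6% and 95.9% were recovered, and for vehicle transgenic against WT 83.7% and 89.8%, on 15067 and 15011 simulated genes. With no gene changed, 0 genes were called in each of the 4 comparisons. The noise was drawn for each gene on its own, without the correlation between genes in the real libraries. These rates therefore need not hold for the real libraries, in which other splits of the WT libraries at 4 and 2 months gave up to 67 calls.

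Alternatives were other scalings (median-of-ratios and upper quartile factors on recovered reads), limma-voom on recovered reads with and without sample quality weights, no filter on low reads or at least 50 reads on average, a pseudocount of 0.1, no trend, all 49 libraries in 1 model, stricter thresholds, and each library left out in turn. Alternatives chosen after seeing the data were 2 surrogate variables, region marker levels as covariates, trimmed mean factors on recovered reads, no robust shrinkage, and fits without sets of libraries. Each comparison was also refitted on 100 splits of its libraries drawn with a fixed seed. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Expression of the human amylin transgene was not analysed here.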

Results

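Poly(A) RNA from the frontal cortex of high fat diet-fed mice was sequenced in 49 libraries. WT mice were on the diet for 2 months (9 libraries) or 4 months (10 libraries), and mice labelled AKO, for amylin knockout, were on it for 4 months (10 libraries). Mice carrying a conditional human amylin transgene, in which tamoxifen is used to switch the transgene on, were on the diet for 4 months and received vehicle (10 libraries) or tamoxifen (10 libraries). The labels place both of these groups 2 months after injection. Median depth was 42.9 M recovered reads in WT at 2 months, 37.8 M in WT at 4 months, 39.8 M in the libraries labelled AKO, 39.8 M in the vehicle group and 47.1 M in the tamoxifen group. Levels are given as log2(normalised reads + 1) with the SD over libraries, and fold changes as differences on that log2 scale with their standard error (SE).

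Iapp encodes amylin, a peptide hormone that pancreatic beta cells release together with insulin (gene ID 15874; chromosome 6, 142298423 to 142303961, plus strand, GRCm38). Iapp reads were present in all 10 libraries labelled AKO, at 5.76 ± 0.18 (SD, n = 10), with 36 to 116 reads per library and 596 reads in 462.2 M. No Iapp read was found among 409.0 M reads of WT at 4 months, 423.9 M of WT at 2 months or 474.7 M of the tamoxifen group, and 1 read was found in the vehicle group, in replicate 16. Against a floor of 3 reads over the WT group at 4 months, Iapp was at least 176-fold higher in the libraries labelled AKO. This direction goes against the knockout label, so the group is called "the libraries labelled AKO" throughout, and directions below are relative to those libraries as labelled. Which part of the Iapp gene the reads came from was not analysed here, and whether the targeting left it transcribed is not given in the sources used here. WT at 2 months lay with WT at 4 months and apart from the libraries labelled AKO in Iapp reads and in the levels of Gabra2 (10.58 ± 0.18, 10.66 ± 0.15 and 11.87 ± 0.12), Nnt (9.67 ± 0.06, 9.75 ± 0.10 and 10.52 ± 0.04) and Fmn1 (9.48 ± 0.32, 9.61 ± 0.11 and 8.12 ± 0.24). This goes against an exchange of labels between the 4-month groups alone. An exchange that took in both WT groups is not excluded by these values and would turn each direction drawn from the label. Ddx3y, a Y-linked gene, was at 11.62 to 11.66 in the group means, and Xist, expressed from the inactive X chromosome of females, reached at most 14 reads in any library.

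**Figure D1:**
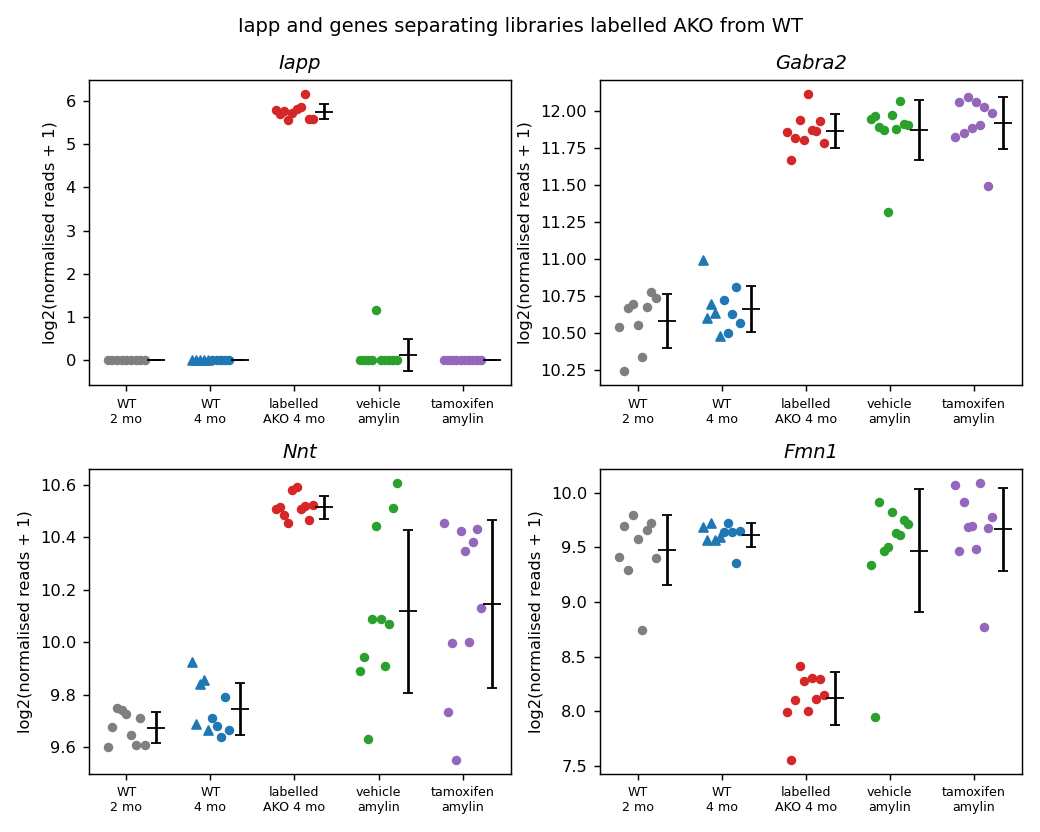
Levels of Iapp, Gabra2, Nnt and Fmn1 in log2(normalised reads + 1) per library (points) by group, with the group mean and SD beside them; triangles are WT libraries numbered 11 to 15. All 10 libraries labelled AKO lie above all 10 WT libraries at 4 months for Iapp, Gabra2 and Nnt and below them for Fmn1.

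The comparison of libraries labelled AKO with WT at 4 months of diet is described as labelled: the label names a loss of amylin, which the Iapp reads go against. Activity-regulated immediate early genes, which neurons transcribe rapidly after stimulation, were lower in the libraries labelled AKO. Egr2 fell by 1.72 (SE 0.24), Fos by 1.66 (SE 0.23), the neuronal transcription factor Npas4 by 1.48 (SE 0.33), Arc, which acts in synaptic plasticity, by 1.22 (SE 0.18) and Fosb by 1.19 (SE 0.15), with n = 10 against 10. Fos was at 9.32 ± 0.37 in the libraries labelled AKO and 10.98 ± 0.63 in WT, 3.15-fold lower. Of the 20 listed immediate early genes, 14 fell and 0 rose over all genes tested, 19 fell adjusted over the list alone, and the list's median change was -0.86. The list passed camera (adjusted p = 3.5e-37) and passed with an estimated correlation (adjusted p = 0.0018). The mean level of the list was 10.35 ± 0.22 in the libraries labelled AKO, 11.25 ± 0.31 in WT at 4 months, 11.39 ± 0.37 in WT at 2 months, 10.83 ± 0.40 in the vehicle group and 10.86 ± 0.54 in the tamoxifen group. Within WT at 4 months it was 0.50 higher in the 5 libraries numbered 11 to 15 than in the 5 numbered 21 to 25 (two-sided exact permutation p = 0.0159), a split chosen after the values were seen. The list's median change was -1.17 against the first set alone and -0.59 against the second alone.

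**Figure D2:**
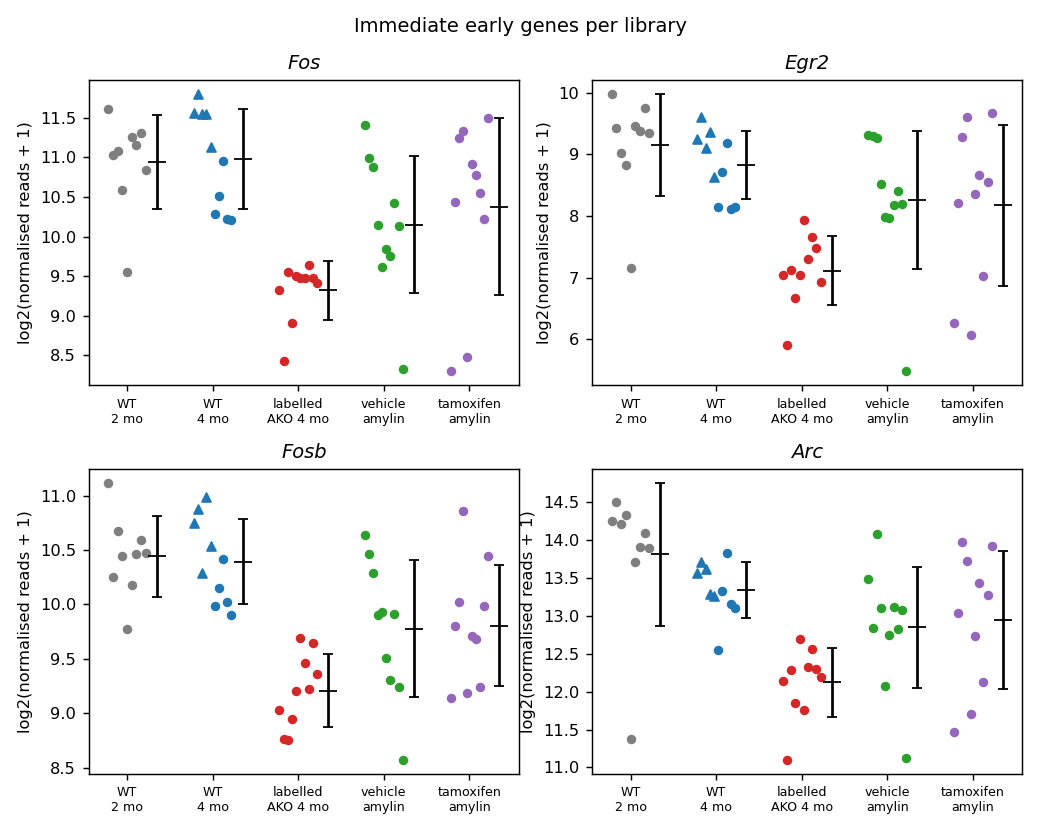
Levels of Fos, Egr2, Fosb and Arc in log2(normalised reads + 1) per library (points) by group, with the group mean and SD beside them; triangles are WT libraries numbered 11 to 15. Fos averaged 9.32 in the libraries labelled AKO and 10.98 in WT at 4 months.

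Outside that list, Gabra2, which encodes the alpha-2 subunit of the GABA-A receptor, rose by 1.21 (SE 0.06), from 10.66 ± 0.15 in WT to 11.87 ± 0.12 in the libraries labelled AKO (chromosome 5, 70957597 to 71095849, minus strand). Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, rose by 0.77 (SE 0.04), and Fmn1, which encodes the actin-nucleating protein formin 1, fell by 1.49 (SE 0.08; chromosome 2, 113327736 to 113716767, plus strand). The pseudogene Hmga2-ps1 rose by 3.0 (SE 0.29), which is uncertain because it can share reads with Hmga2. The chemokine Ccl28 rose by 1.07 (SE 0.17) and Hes5, a Notch target gene, by 0.98 (SE 0.18). Cyr61, a secreted matrix-associated protein, fell by 1.72 (SE 0.36), and the stress-responsive transcription factor Atf3 fell by 1.43 (SE 0.32). Of 18 clock genes, 2 rose and 1 fell over all genes tested, and 5 rose and 2 fell adjusted over the list alone: Dbp rose by 0.59 (SE 0.10), Nr1d1 rose by 0.35 (SE 0.05) and Nfil3 fell by 0.66 (SE 0.10). That list did not pass camera (adjusted p = 0.23), which tests a shift in 1 direction and cannot decide on members that move both ways. Of its 18 members 9 had an unadjusted p under 0.05. A test of change in either direction (limma fry, mixed), which does not compare with other genes, gave an unadjusted p of 1.8e-09. The list of glucocorticoid-induced genes had 2 of 16 members that fell (6 adjusted over the list alone), Cdkn1a and Pdk4, by 0.67 (SE 0.14) and 0.37 (SE 0.09). It passed camera (adjusted p = 8.9e-06), and adjusted p = 0.30 with an estimated correlation. Ide, which encodes the insulin-degrading enzyme that also degrades amylin, rose by 0.54 (SE 0.11).

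All 16 tested markers of myelinating oligodendrocytes had lower values in the libraries labelled AKO, with a median of -0.18. Mean Mobp was 12.72 ± 0.19 in these libraries, 13.12 ± 0.14 in WT at 4 months and 12.80 ± 0.39 in WT at 2 months. Mobp and Cldn11 fell by 0.40 (SE 0.07) and 0.27 (SE 0.06). They were the 2 markers that passed over all genes tested; 15 fell adjusted over the list alone (camera adjusted p = 7.7e-13; adjusted p = 0.12 with an estimated correlation). Of 17 chaperone genes, 2 fell, the constitutive chaperone Hspa8 by 0.15 (SE 0.03) and the small heat shock protein Cryab by 0.26 (SE 0.06), and 10 fell adjusted over the list alone (camera adjusted p = 1.9e-08; adjusted p = 0.12 with an estimated correlation). Of 24 endoplasmic reticulum stress genes, Atf3 and Calr fell, Calr by 0.21 (SE 0.04), and 6 fell adjusted over the list alone (camera adjusted p = 9.6e-05; adjusted p = 0.32 with an estimated correlation). Of 25 cholesterol synthesis genes, 1 rose, Acat2, by 0.20 (SE 0.04), and 11 rose adjusted over the list alone (camera adjusted p = 1.2e-08; adjusted p = 0.12 with an estimated correlation). Striatal projection neuron markers had higher values in the libraries labelled AKO for all 14 tested members, with a median of 0.38. Of these 0 passed over all genes by limma or limma-voom or adjusted over the list alone, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0040; adjusted p = 0.63 with an estimated correlation).

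The other 9 lists past camera had 0 members past the threshold by limma or limma-voom. Cytosolic ribosomal protein genes, which can share reads with processed pseudogenes, had higher values in the libraries labelled AKO in 75 of 77 members, with a median of 0.08, 25 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 1.7e-12; adjusted p = 0.54 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher in 60 of 67, with a median of 0.05, 7 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 5.0e-06; adjusted p = 0.60 with an estimated correlation). Microglia markers were higher in 13 of 16, with a median of 0.08, 7 at an unadjusted p under 0.05 and 2 adjusted over the list alone (camera adjusted p = 0.0029; adjusted p = 0.41 with an estimated correlation). Interferon-stimulated genes were higher in 18 of 24, with a median of 0.18, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.0101; adjusted p = 0.63 with an estimated correlation). Oligodendrocyte precursor markers were lower in 8 of 12, with a median of -0.10, 5 at an unadjusted p under 0.05 and 3 adjusted over the list alone (camera adjusted p = 0.0052; adjusted p = 0.32 with an estimated correlation). Endothelial markers were lower in 12 of 14, with a median of -0.11, 3 at an unadjusted p under 0.05 and 1 adjusted over the list alone (camera adjusted p = 0.0037; adjusted p = 0.32 with an estimated correlation). Inhibitory neuron markers were lower in 11 of 15, with a median of -0.13, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.0261; adjusted p = 0.12 with an estimated correlation). Synaptic vesicle and glutamate receptor genes were lower in 23 of 30, with a median of -0.05, 3 at an unadjusted p under 0.05 and 1 adjusted over the list alone (camera adjusted p = 0.0050; adjusted p = 0.58 with an estimated correlation). Sex chromosome genes were lower in 6 of 8, with a median of -0.07, 2 at an unadjusted p under 0.05 and 1 adjusted over the list alone (camera adjusted p = 0.0277; adjusted p = 0.30 with an estimated correlation).

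In total 120 of 15185 genes passed, 43 higher and 77 lower in the libraries labelled AKO (limma-trend, Benjamini-Hochberg adjusted p 0.05), and limma-voom called 126. By camera 16 of 33 lists passed, 6 upward and 10 downward, and 1, the immediate early genes, passed with an estimated correlation. Within 10 Mb of Iapp 2 of 83 tested genes passed, Iapp and Ldhb, against 112 of 14553 elsewhere (two-sided Fisher's exact p = 0.137). Among the libraries labelled AKO, the count was 62 without replicate 8, 78 without replicate 6, 78 without replicate 13 and 206 without replicate 15, and it was 77 without WT replicate 14 and 73 without WT replicate 21. It was 50 with all 49 libraries in 1 model. Cyp2g1, an enzyme of the olfactory epithelium looked at after the data were seen, was highest in replicates 14 and 19 of the libraries labelled AKO, at 12.30 and 11.34, against at most 8.98 in the other 8 and 7.67 in WT at 4 months. Without these 2 libraries, a choice made after seeing the data, 62 genes passed. In other fits chosen then, 79 genes passed with 2 surrogate variables, 156 with the WT libraries numbered 21 to 25 alone and 138 with those numbered 11 to 15 alone, of which 44, 49 and 59 were among the 120.

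The comparison of tamoxifen with vehicle addresses the induction of human amylin, 2 months after injection. Expression of the transgene was not analysed here, so its induction was not checked in these libraries. No gene passed among 15270 (limma-trend), with 503 at an unadjusted p under 0.05 (3.3%), and limma-voom called 0 with and without sample quality weights. Mapk15, an atypical MAP kinase, had the largest difference among the 10 genes with the smallest p, at 2.16 (SE 0.51, n = 10 against 10). Nptx2, a neuronal pentraxin of excitatory synapses, was at 11.51 ± 0.22 with tamoxifen and 11.91 ± 0.19 with vehicle. This was a difference of -0.39 (SE 0.09). The ciliary gene Zmynd10 differed by 0.62 (SE 0.16), the kinetochore gene Zwilch by 0.39 (SE 0.09) and Yrdc by -0.18 (SE 0.04), and the adjusted p of each was 0.9998. The median 95% interval of a gene reached 0.174 to either side, and in simulated reads 69.4% of genes changed 1.5-fold and 86.0% of genes changed 2-fold were recovered, among 15119 genes.

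Among gene groups, 0 of 641 list members passed over all genes by limma or limma-voom, and 13 had an unadjusted p under 0.05. Adjusted over the list alone, 1 of 20 immediate early genes fell, Nptx2. All 16 myelinating oligodendrocyte markers had higher values with tamoxifen, with a median of 0.19 (camera adjusted p = 3.4e-06; adjusted p = 0.97 with an estimated correlation). Nuclear oxidative phosphorylation genes had lower values in 66 of 67 members, with a median of -0.06 (camera adjusted p = 2.0e-13; adjusted p = 0.87 with an estimated correlation). Choroid plexus and ependymal markers had a median of 0.44 (camera adjusted p = 0.0041; adjusted p = 0.87 with an estimated correlation) and interferon-stimulated genes of -0.17 (camera adjusted p = 0.0160; adjusted p = 0.998 with an estimated correlation). Olfactory bulb markers had a median of -0.52 (camera adjusted p = 0.25), and their level per library ran from -1.27 to 1.53 with tamoxifen and from -1.58 to 1.88 with vehicle. The direct effect of tamoxifen is not separated from induction in this design, because tamoxifen-treated mice without the transgene were not analysed here.

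The effect in the libraries labelled AKO and that of tamoxifen were compared in 1 model of 40 libraries. They differed for 6 of 15665 genes (885 at an unadjusted p under 0.05). Iapp, Hmga2-ps1, Gabra2 and Nnt had the higher and Cyr61 and Fmn1 the lower effect in the libraries labelled AKO. For Gabra2 the effects were 1.21 and 0.05 (difference 1.16, SE 0.10, adjusted p = 3.0e-10) and for Fmn1 -1.49 and 0.19 (difference -1.69, SE 0.22, adjusted p = 1.4e-05). Mean Gabra2 was 11.88 with vehicle and 11.92 with tamoxifen, near the 11.87 of the libraries labelled AKO and above the 10.66 of WT at 4 months. The Gabra2 effects were thus taken from unlike baselines. Across 15084 genes, which are not independent replicates, the effects correlated with Pearson's r = 0.228 and Spearman's rho = 0.198. Pearson's r was 0.144 with no filter on low reads and 0.283 with at least 50 reads on average. With library labels permuted within each comparison, r ran from -0.426 to 0.439 over 100 draws (permutation p = 0.307 for each).

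WT mice at 4 months of diet were compared with WT mice at 2 months, in which time on diet is not separated from age. Microglial genes were higher at 4 months. Itgam, which encodes the CD11b integrin, rose by 0.26 (SE 0.04, n = 10 against 9), the microglial receptor P2ry12 by 0.26 (SE 0.05) and Fcrls by 0.31 (SE 0.05). Of 16 microglia markers 9 rose and 0 fell, and 12 rose adjusted over the list alone (camera adjusted p = 2.9e-09; adjusted p = 0.19 with an estimated correlation). Of 17 disease-associated microglia genes 7 rose (10 adjusted over the list alone), among them Axl by 0.22 (SE 0.05) and the lipid carrier Apoe by 0.28 (SE 0.06), which astrocytes also express (camera adjusted p = 1.1e-05; adjusted p = 0.20 with an estimated correlation).

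Of 14 astrocyte markers 7 rose and 0 fell (8 rose adjusted over the list alone), including the gap junction gene Gja1 by 0.28 (SE 0.05) and the water channel Aqp4 by 0.34 (SE 0.08) (camera adjusted p = 1.7e-04; adjusted p = 0.21 with an estimated correlation). The complement gene C4b rose by 0.65 (SE 0.15), 1 of 3 reactive astrocyte genes that rose of 15 (4 adjusted over the list alone; camera adjusted p = 0.0219; adjusted p = 0.29 with an estimated correlation). Endothelial markers rose in 3 of 14, such as the adhesion molecule Pecam1 by 0.26 (SE 0.06), with 9 that rose and 2 that fell adjusted over the list alone (camera adjusted p = 0.0038; adjusted p = 0.19 with an estimated correlation). Mural cell markers rose in 2 of 12 (3 adjusted over the list alone), Vtn by 0.34 (SE 0.07) and Rgs5 by 0.28 (SE 0.07) (camera adjusted p = 4.3e-04; adjusted p = 0.21 with an estimated correlation). Markers of further cell types also had higher values. Of 12 oligodendrocyte precursor markers 10 were higher, and 1 rose, C1ql1 by 0.47 (SE 0.14), with 2 adjusted over the list alone (camera adjusted p = 0.0241; adjusted p = 0.29 with an estimated correlation). All 16 myelinating oligodendrocyte markers had higher values, with a median of 0.25. Over all genes 1 rose, Opalin by 0.58 (SE 0.17), with 0 by limma-voom and 7 adjusted over the list alone (camera adjusted p = 6.4e-05, and adjusted p = 0.44 with an estimated correlation). All 15 leptomeningeal and fibroblast markers had higher values, with a median of 0.38. Of these 1 rose, Dcn by 0.51 (SE 0.16), with 0 by limma adjusted over the list alone or by limma-voom and 10 at an unadjusted p under 0.05 (camera adjusted p = 7.2e-05; adjusted p = 0.43 with an estimated correlation). All 11 choroid plexus and ependymal markers had higher values, with a median of 0.65, of which 0 passed by limma or limma-voom or adjusted over the list alone, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0064; adjusted p = 0.29 with an estimated correlation). Cytosolic ribosomal protein genes rose in 26 of 77 over all genes and 59 adjusted over the list alone, with a median of 0.13 (camera adjusted p = 6.2e-20; adjusted p = 0.29 with an estimated correlation); Rps3a1 rose by 0.23 (SE 0.04). Values of ribosomal protein genes are uncertain, since they can share reads with processed pseudogenes. Nuclear oxidative phosphorylation genes had higher values in 52 of 67, with a median of 0.03, while the 1 that passed, Atp5g1, fell by 0.13 (SE 0.03). None passed by limma adjusted over the list alone, with 7 at an unadjusted p under 0.05 and 1 called by limma-voom (camera adjusted p = 0.0367; adjusted p = 0.72 with an estimated correlation).

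A few neuronal genes were lower at 4 months. The transcription factor Neurod2 fell by 0.35 (SE 0.08) and Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, by 0.20 (SE 0.06). They were the 2 of 15 excitatory neuron markers that passed, with 7 that fell adjusted over the list alone (camera adjusted p = 0.0172; adjusted p = 0.30 with an estimated correlation). The synaptic genes Nlgn2 and Syn1 fell by 0.19 (SE 0.05) and 0.23 (SE 0.07), the 2 of 30 synaptic vesicle and glutamate receptor genes that fell over all genes, against 6 that fell and 1 that rose adjusted over the list alone (camera adjusted p = 0.0064; adjusted p = 0.58 with an estimated correlation). Cort, the inhibitory neuropeptide cortistatin, fell by 0.47 (SE 0.10) and neuropeptide Y, Npy, by 0.15 (SE 0.05), the 2 of 15 inhibitory neuron markers that passed (2 adjusted over the list alone). That list did not pass camera (adjusted p = 0.68), with 7 members higher and 8 lower, a median of -0.08 and a mean of 0.05. Creld2 fell by 0.33 (SE 0.09), the 1 of 24 endoplasmic reticulum stress genes that passed (1 adjusted over the list alone; camera adjusted p = 0.0367; adjusted p = 0.63 with an estimated correlation). Immediate early genes were lower in 14 of 20, with a median of -0.20. The list had 0 members past the threshold by limma or limma-voom or adjusted over the list alone, 5 at an unadjusted p under 0.05 (camera adjusted p = 0.0499; adjusted p = 0.63 with an estimated correlation). Nr1d1, a repressor of the circadian clock, fell by 0.48 (SE 0.05), and Cry1 rose by 0.23 (SE 0.05), the 2 of 18 clock genes that passed (1 each way adjusted over the list alone; camera adjusted p = 0.38). Among the largest changes, the acute-phase protein Lbp rose by 0.97 (SE 0.26), the MHC class II gene H2-Aa by 0.96 (SE 0.26) and the meningeal collagen gene Col8a2 by 0.86 (SE 0.23), while Trim72 fell by 1.06 (SE 0.26) and Tnnc1, a muscle troponin gene, by 0.89 (SE 0.19). Beside these groups, olfactory bulb markers had a median of 0.79 and striatal projection neuron markers of 0.51, with 0 members past the threshold by limma or limma-voom or adjusted over the list alone and 1 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0259 and 0.0367; adjusted p = 0.61 and 0.66 with an estimated correlation).

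In total 1330 of 15159 genes passed, 697 higher and 633 lower at 4 months, of which 100 changed at least 1.5-fold, and 20 of 33 lists passed camera and 0 with an estimated correlation. The split moved with the scaling. Upper quartile factors gave 807 higher and 502 lower, trimmed mean factors, added after seeing the data, 668 and 716, and limma-voom 649 and 715. Iapp had 0 reads in both groups and was not tested. The count was 772 without WT 4-month replicate 12, and 777, 805, 816, 793 and 2846 without WT 2-month replicates 32, 33, 34, 35 and 37. In fits chosen after seeing the data it was 73 with region marker levels as covariates, 90 with 2 surrogate variables, 36 with the WT 4-month libraries numbered 21 to 25 alone and 1148 with those numbered 11 to 15 alone. It was 875 with all 49 libraries in 1 model and 2375 with sample quality weights.

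**Figure D3:**
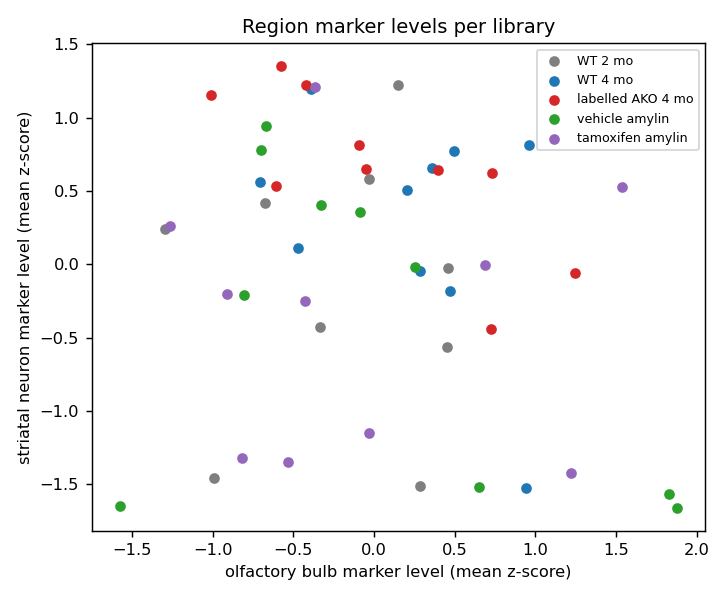
Level of olfactory bulb markers (x axis) against striatal projection neuron markers (y axis), each as the mean z-score of the list over the 49 libraries, 1 point per library, coloured by group. Within the vehicle group the olfactory bulb level runs from -1.58 to 1.88 and the striatal level from -1.66 to 0.95.

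Vehicle-treated transgenic mice were compared with WT at 4 months, where line, injection and any batch are not separated. Genes of myelinating oligodendrocytes were lower in the vehicle-treated transgenic mice. Ugt8a, which makes the myelin lipid galactosylceramide, fell by 0.79 (SE 0.12, n = 10 against 10), from 10.97 ± 0.12 to 10.18 ± 0.38. Transferrin, Trf, fell by 0.68 (SE 0.11) and Opalin by 0.97 (SE 0.24). Mean Mobp was 13.12 in WT at 4 months and 12.40 to 12.80 in the other groups. The lower myelin values here and in the libraries labelled AKO thus share 1 high group. Of 16 myelinating oligodendrocyte markers 15 fell over all genes and 16 adjusted over the list alone, with a median of -0.63 (camera adjusted p = 2.3e-19; adjusted p = 0.11 with an estimated correlation). Of 12 oligodendrocyte precursor markers 5 fell (6 adjusted over the list alone), with the lineage factors Olig1 and Olig2 falling by 0.36 (SE 0.06) and 0.31 (SE 0.07) (camera adjusted p = 6.2e-05; adjusted p = 0.17 with an estimated correlation). Beside them, all 14 striatal projection neuron markers had lower values, with a median of -0.75 and 0 members past the threshold by limma or limma-voom or adjusted over the list alone, 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0018; adjusted p = 0.70 with an estimated correlation). Vehicle replicates 1, 3, 5 and 40 were the lowest of their group in both the striatal level (-1.664 to -1.515) and the myelinating oligodendrocyte level (-2.245 to -1.504). The brain region in the tissue is therefore not separated from the myelin changes either. Choroid plexus and ependymal markers were lower in 8 of 10, with a median of -0.68, and leptomeningeal and fibroblast markers in 14 of 15, with a median of -0.38. Both had 0 members past the threshold by limma or limma-voom or adjusted over the list alone, with 5 and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0052 and 0.0028; adjusted p = 0.29 and 0.70 with an estimated correlation). Of 14 endothelial markers 2 fell (3 adjusted over the list alone), the receptor Tek by 0.35 (SE 0.09) and Pecam1 by 0.25 (SE 0.07) (camera adjusted p = 0.0411; adjusted p = 0.63 with an estimated correlation). Of 77 cytosolic ribosomal protein genes 1 fell, Rps6, by 0.16 (SE 0.04). None fell by limma adjusted over the list alone, with 15 at an unadjusted p under 0.05, 1 called by limma-voom and a median of -0.04 (camera adjusted p = 0.0104; adjusted p = 0.84 with an estimated correlation).

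**Figure D4:**
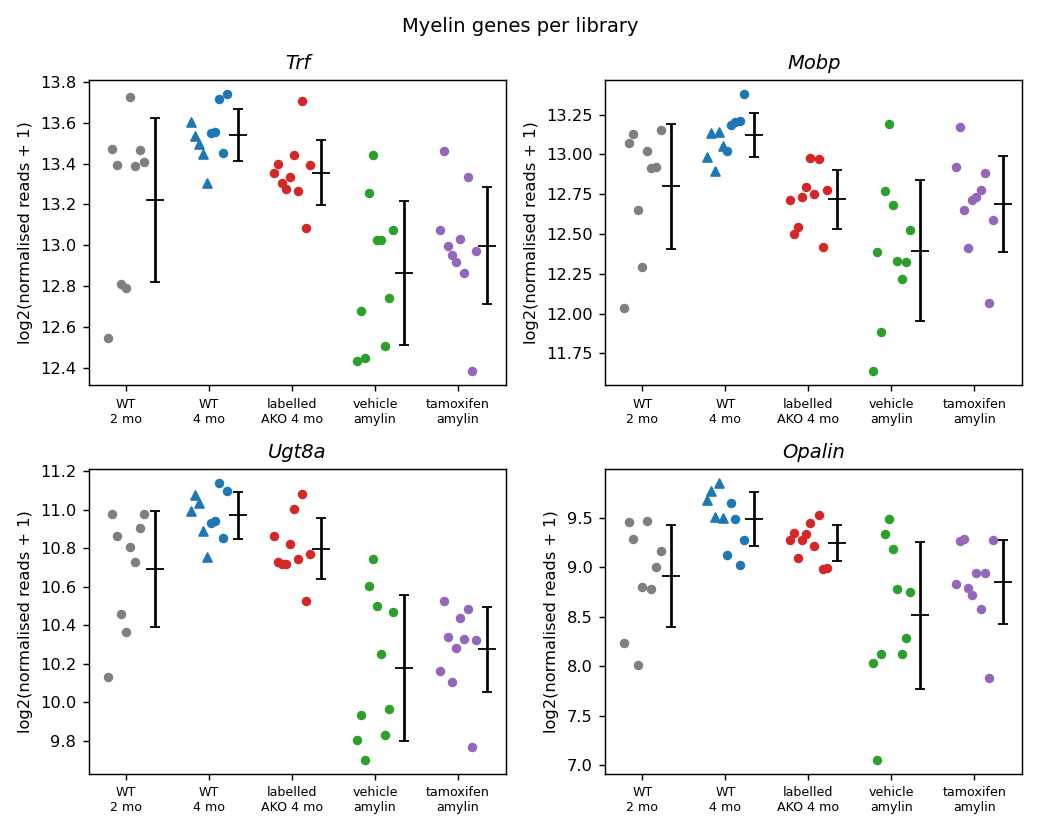
Levels of Trf, Mobp, Ugt8a and Opalin in log2(normalised reads + 1) per library (points) by group, with the group mean and SD beside them; triangles are WT libraries numbered 11 to 15. Ugt8a averaged 10.18 in the vehicle group and 10.97 in WT at 4 months.

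Chaperone genes fell in 7 of 17 over all genes and 13 adjusted over the list alone (camera adjusted p = 3.0e-09; adjusted p = 0.086 with an estimated correlation), including Cryab by 0.62 (SE 0.10), Chordc1 by 0.34 (SE 0.05) and Hspa8 by 0.21 (SE 0.04). Endoplasmic reticulum stress genes fell in 5 of 24 (7 adjusted over the list alone), such as the chaperone Hsp90b1 by 0.29 (SE 0.05) and Chac1 by 0.48 (SE 0.08) (camera adjusted p = 9.3e-06; adjusted p = 0.33 with an estimated correlation). Of 20 immediate early genes 1 fell, Egr4, by 0.51 (SE 0.15), and 0 by limma adjusted over the list alone or by limma-voom, with 7 at an unadjusted p under 0.05 (camera adjusted p = 6.2e-05; adjusted p = 0.35 with an estimated correlation). Disease-associated microglia genes fell in 2 of 17 (4 adjusted over the list alone), Ctsz by 0.25 (SE 0.05) and the receptor Clec7a by 1.42 (SE 0.33) (camera adjusted p = 0.0018; adjusted p = 0.18 with an estimated correlation). Of 25 insulin and IGF signalling genes 2 rose, Igfbp3, an IGF binding protein, by 0.38 (SE 0.07) and the neuronal glucose transporter Slc2a3 by 0.13 (SE 0.04), with 6 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.086 with an estimated correlation). The largest rises were in Tmem181b-ps, by 1.88 (SE 0.11), Wdfy1, by 1.55 (SE 0.20), and Dynlt1b, by 1.40 (SE 0.21). They were followed by Tmem40, by 1.24 (SE 0.20), Gabra2, by 1.21 (SE 0.08), and Cd59a, a complement inhibitor, by 1.14 (SE 0.15). Tmem181b-ps and Dynlt1b are uncertain because near-identical copies can share their reads. Nr1d1 rose by 0.44 (SE 0.08), and the matricellular gene Thbs4 and Cyr61 fell by 1.43 (SE 0.33) and 1.35 (SE 0.35). Mean Nr1d1 was 11.73 in WT at 4 months and 12.09 to 12.21 in the other groups. Its changes in all comparisons with WT at 4 months thus share 1 low group.

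In total 938 of 15129 genes passed, 392 higher and 546 lower in the vehicle-treated transgenic mice, and 12 of 33 lists passed camera, 0 with an estimated correlation. The single Iapp read of the vehicle group allowed no comparison with the 0 reads of WT. The count was 1494 without vehicle replicate 3 and 2507 with sample quality weights. In fits chosen after seeing the data it was 396 with the WT libraries numbered 21 to 25 alone, 162 with those numbered 11 to 15 alone, and 2752 without vehicle replicates 1 and 3, which had the highest olfactory bulb marker levels.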

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

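Libraries that stood apart were found by a planned rule; all tests that weigh an explanation below were chosen only after the result was seen, except those of region markers for the immediate early genes and for the WT counts and that of fewer libraries, whose outcomes were stated first.

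Of 302 pairs of a named gene and a group, 28 had a library far from the others, where chance gives about 1 in 20. Levels are in log2(normalised reads + 1). Among libraries labelled AKO these were replicate 16 for Iapp (6.17, others 5.56 to 5.86), replicate 6 for Hmga2-ps1 (6.12) and Fmn1 (7.55), replicate 15 for Lamb3 (6.05) and Pdk4 (8.36), and replicate 21 for Nr1d1 (12.40, others 11.94 to 12.15). In WT at 4 months they were replicate 13 for Lamb3 (4.72), Slc2a3 (12.66), Atp10b (6.81) and Olig2 (10.73), replicate 24 for Fmn1 (9.36), replicate 22 for C1ql1 (7.97), replicate 15 for Tek (9.20) and replicate 11 for Cd59a (7.03). In WT at 2 months, replicate 35 was low for Lbp (3.83), Col2a1 (3.53) and Tek (8.72) and high for Creld2 (10.35). Replicate 37 of that group was high for Fbln5 (8.44), Ifi27 (10.50), Rps3a1 (13.79), Rps27a (13.03) and Rpl10 (13.10). In the vehicle group, replicate 16 was low for Wdfy1 (9.26, others 10.69 to 11.81) and Gabra2 (11.32, others 11.87 to 12.07), replicate 3 low for Col8a2 (4.58), replicate 11 high for Fgfr3 (12.76) and replicate 1 high for H2-Eb1 (7.77).

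The effect in the libraries labelled AKO differed from that of tamoxifen, by a test of the difference itself, by 5.87 for Iapp, 2.97 for Hmga2-ps1, 1.16 for Gabra2, 0.74 for Nnt, -2.45 for Cyr61 and -1.69 for Fmn1. The value for Iapp depends on the 1 added before logs and is no bound.

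Immediate early genes were lower in the libraries labelled AKO, with a mean level of 10.35 against 11.25 in WT at 4 months, and the vehicle and tamoxifen groups lay between at 10.83 and 10.86. The WT libraries numbered 11 to 15 as the whole cause are argued against by the median change of -0.59 against the WT libraries numbered 21 to 25 alone (exact permutation p = 3.3e-04 for the list level, the smallest that 10 against 5 can give), although the median against all WT was -0.86. Tissue of other brain regions as the whole cause is argued against by a median of -0.75 with region marker levels as covariates. Time of day at collection cannot be told apart from genotype: 3 of 18 clock genes passed, 9 had an unadjusted p under 0.05, and collection times are not given in the sources used here. Genotype and handling stay open as untested explanations.

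Complete separation of the libraries labelled AKO from WT at 4 months held for 19 of 15185 tested genes, where chance gives 0.0011%, and 18 of these passed: Iapp, 5 immediate early genes, Gabra2, Nnt, Fmn1 and Hmga2-ps1, which changed at least 1.5-fold, Nr1d1, and, named after their values were seen, Gadd45b, Gadd45g, Dusp6, Setd7, Gtf2e2, Denr and Nudt11. For the 12 besides Iapp and the immediate early genes, a segment carried along with the targeted Iapp locus is argued against, since 0 of them lie on chromosome 6. This does not cover Ldhb, which passed, is not among the 12 and lies within 1 Mb of Iapp, so a carried segment stays open for it. A difference between mouse lines apart from Iapp cannot be told apart from genotype, as the design has 1 line per genotype. In 1 of the 12 genes, Gabra2, all 20 transgenic libraries lay beyond all 19 WT libraries on the side of the libraries labelled AKO. The Gabra2 shift was thus not particular to the libraries labelled AKO. For Nnt 15 of 20 lay beyond, for Hmga2-ps1 5, for Fmn1 1 and for the other 8 genes 1 to 9. Of these 8, all but Gadd45b are left undecided by this bound. Only 0 (Nudt11) to 7 (Dusp6) of the 10 libraries labelled AKO themselves lay beyond all WT libraries for them. A candidate explanation for Gabra2 and Nnt is a mixed C57BL/6 substrain background, since the C57BL/6J substrain is known to carry deletions in both genes. The labels name no strain, and this explanation was not tested. A wider role of such segments stays open as well, with 22 of 114 called genes within 1 Mb of another called gene against 8 to 29 in 95% of 10000 random sets (median 18, p = 0.2792).

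The WT count at 4 against 2 months dropped from 1330 to 36 without the WT 4-month libraries numbered 11 to 15. The median change of the 1330 genes was then 0.201 (median SE 0.068) against 0.232 (0.059), so both smaller changes and larger errors ended calls. All 1330 genes kept their direction. They were picked in a fit that held the remaining libraries too, so this was nearly fixed in advance and is no support for the calls. Fewer libraries in the fit can give such a drop, as 36 of 100 random sets of 5 WT libraries left out gave as few calls (0 to 1493, median 73.5), but numbers 11 to 15 alone, as many libraries, gave 1148 calls (713 among the 1330) with a median change of 0.264 (median SE 0.073), so a difference between these libraries stays open too. For tissue of other brain regions, 10 of 100 fits with shuffled marker levels gave as few calls as the 73 with the real levels, which met the bound stated beforehand against that explanation. That bound could not decide, because shuffled levels alone gave 0 to 3087 calls (median 848), and so this explanation stays open. With the real levels the median change of the 1330 genes went from 0.232 to 0.158 and its median SE from 0.059 to 0.062, so the calls ended mainly through smaller changes.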

How the results depend on the processing

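The surrogate variables, region marker levels, trimmed mean factors, fits without robust shrinkage and sets of left-out libraries were chosen only after the result was seen; the other settings were planned. Tamoxifen against vehicle gave 0 genes under each setting and each library left out (0 to 0), with 503 at an unadjusted p under 0.05 in the planned fit. None of the named genes' changes turned direction, and of those past the threshold in libraries labelled AKO against WT, WT at 4 against 2 months and vehicle transgenic against WT, 7 of 32, 1 of 66 and 9 of 54 passed in each setting run. For all values below the cause was not tested unless fewer libraries or a stricter threshold is the setting itself. With an estimated inter-gene correlation 0 of 4 lists passed for tamoxifen, 1 of 16 for libraries labelled AKO, 0 of 20 for WT at 4 against 2 months and 0 of 12 for vehicle transgenic. At adjusted p 0.01 the counts were 35, 203 and 331 genes for libraries labelled AKO, WT time and vehicle transgenic, and with a change of at least 1.5-fold 32, 100 and 118. All 49 libraries in 1 model gave 50 for libraries labelled AKO and 875 for WT time, and sample quality weights 2375 for WT time and 2507 for vehicle transgenic. The 2 surrogate variables gave 79 genes for libraries labelled AKO (44 shared with the 120), 90 genes and 10 lists for WT time, and 21 genes for the effect in libraries labelled AKO minus that of tamoxifen (6). Region marker levels gave 73 genes and 7 lists for WT time. The WT libraries numbered 21 to 25 alone gave 36 genes for WT time and 396 genes and 7 lists for vehicle transgenic, and those numbered 11 to 15 alone 162 genes for vehicle transgenic. For libraries labelled AKO they gave 156 and 138 genes, of which 49 and 59 were among the 120. Leaving out replicates 14 and 19 of the libraries labelled AKO gave 62, and leaving out vehicle replicates 1 and 3 gave 2752 genes and 19 lists for vehicle transgenic. Leaving out 1 library at a time gave 62 (without replicate 8) to 206 (without replicate 15) for libraries labelled AKO, 772 (without WT 4-month replicate 12) to 2846 (without WT 2-month replicate 37) for WT time, and 651 (without vehicle replicate 40) to 1494 (without vehicle replicate 3) for vehicle transgenic. The other scalings, filters and pseudocount kept each count within 1.5 times.

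Libraries labelled AKO and WT share 5 title numbers. With these as a replicate block 12 genes passed, all among the 120, in a fit of 10 libraries. Deviations of same-numbered libraries correlated at 0.048, -0.236, -0.290, 0.138 and 0.107, and none was highest with its own number. These values show no sign of pairing, but 5 numbers are too few to exclude it. Not run were the planned count-model tests, in whose place limma-voom was run on the recovered reads, the planned surrogate variable package, in whose place surrogate variables were taken from the residuals, their versions of the correlation between effects, and Xist as a covariate, whose level was near 0. Depth limits Iapp below 3 reads per group.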

Other observations

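The splits of libraries were planned and their reading was set only after the result was seen; the comparison of title numbers within WT was chosen after the values were seen.

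Members of further groups passed between WT at 4 and 2 months, though the interferon-stimulated list and the amyloid and tau list did not pass camera. Of 15 MHC and antigen presentation genes 4 rose (8 adjusted over the list alone), including the immunoproteasome subunit Psmb8 by 0.39 (SE 0.10) and Tapbp, which loads peptides onto MHC class I, by 0.29 (SE 0.06) (camera adjusted p = 2.9e-04; adjusted p = 0.29 with an estimated correlation). Of 18 oxidative stress response genes 5 rose (5 rose and 1 fell adjusted over the list alone), including the cystine transporter Slc7a11 by 0.42 (SE 0.06) and the peroxiredoxin Prdx6 by 0.22 (SE 0.04) (camera adjusted p = 0.0289; adjusted p = 0.26 with an estimated correlation). Of 24 interferon-stimulated genes 3 rose (4 adjusted over the list alone), Ifi27 by 0.32 (SE 0.06), and Ifit3b by 0.50 (SE 0.12) and Ifit3 by 0.44 (SE 0.13), which are near-identical copies and uncertain (camera adjusted p = 0.11). The cholesterol exporter Abca1 rose by 0.47 (SE 0.10), and Ncstn, a subunit of gamma-secretase, fell by 0.16 (SE 0.04), in a list of 23 amyloid and tau pathway genes of which 2 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.95). In vehicle-treated transgenic mice against WT, the peroxiredoxin Prdx6 fell by 0.25 (SE 0.05), the MHC class II gene H2-Eb1 by 0.79 (SE 0.22) and the microglial receptor Fcrls by 0.46 (SE 0.07), while the erythroid gene Alas2 rose by 0.88 (SE 0.19).

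In 3 comparisons only the real split of 100 gave as many genes, which argues against chance for these counts. They were 120 for libraries labelled AKO against WT (highest other 46), 1330 for WT at 4 against 2 months (67) and 938 for vehicle transgenic against WT (2), each 1 of 100. The same held for the 6 genes that differed between the effect in libraries labelled AKO and that of tamoxifen (1 of 100, highest other 1). With 100 splits, 1 of 100 is the smallest share possible. A split of WT at 4 months by title number, chosen after the values were seen, also gave 1 of 100, so such a share does not tell the cause. For tamoxifen against vehicle the real count was 0, which 100 of 100 splits reach by construction (highest other 1), so the splits decide nothing there. Counts of lists past camera at the preset correlation are another matter. As many lists came from 99 of 100 splits for tamoxifen against vehicle (4, highest other 19), 6 for libraries labelled AKO against WT (16, highest other 19) and 25 for vehicle transgenic against WT (12, highest other 18), so chance cannot be excluded for them, and from 1 of 100 for WT at 4 against 2 months (20, highest other 19). Why a split of the tamoxifen and vehicle libraries gave 19 lists where the real one gave 4 was not tested. With an estimated correlation in place of the preset one, 0 lists passed in the real split of tamoxifen against vehicle. For libraries labelled AKO against WT 1 list passed, the immediate early genes, and 0 passed in each of the other comparisons.

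Within WT at 4 months, libraries numbered 21 to 25 differed from those numbered 11 to 15 in 64 of 15205 genes, and 1 of 100 splits gave as many. What the numbers stand for is not given in the sources used here. In the vehicle group, replicate 16 held the single Iapp read. It had an Nnt level of 10.44 and an Fmn1 level of 9.50, against means of 10.12 and 9.47 in its group.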
